A study of Mus musculus with 6 samples.

How the data were processed

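RNA of 6 tumour samples, 3 of the oleanolic acid group and 3 of the solvent group, was extracted with Trizol and made into libraries with the NEBNext Ultra II RNA kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.5, HTSeq 0.9.1, DESeq 1.30.0 and the mouse build mm9, without saying what each was used for, and whether counting used strand is not given in the sources used here. The deposited table holds, for 21899 genes and each library, a raw read count and an FPKM value (fragments scaled to gene length and library size), both made by the authors. All per-library columns were matched to a sample by title. Groups and replicate numbers were taken from the sample titles.

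In the deposited table the values and the gene annotation were not in the same order, and this decided how genes were named. Down the table the counts of OA replicate 1 never rise and the gene identifiers never fall, which 1 order of genes cannot give. In each row the count divided by the product of column total and FPKM, times the constant of the FPKM unit, returns the gene length that the authors divided by. Over 17169 rows with enough precision it lay within 0.000268 bp of a whole number, and in 12407 of 12407 rows with 10 or more reads in every library it was the same in all 6. Only 3 rows had the length printed beside them, yet no length occurred more often than in the table's length column. The gene symbols printed beside the values were therefore not used. A row was given a gene where exactly 1 gene was possible from its length, from the rising order of identifiers among rows tied in the sort column (1485 of 1485 neighbouring pairs of rows known by length alone followed it) and from 1 row per gene. This met 0 contradictions and named 13639 of 17321 rows with reads, 3233 of them by length alone. In 3 simulated tables between 12298 and 12324 rows were named, 0 of them wrongly. These tables were built under the same rules, so they check the procedure and not whether the deposited table follows the rules. Members of 36 of the fixed lists were compared over the 6 libraries: the median over lists of the median correlation between members was 0.469 with the recovered names and 0.009 with the printed ones, and was higher with the recovered names in 34 of 36 lists. Rows that stayed open between several genes were kept in library sizes, scaling and tests, and out of gene lists and names. Identifiers matched GENCODE M21 for 21795 genes, of which 97.4% had the same symbol and 97.7% the same exon length. Start positions were those of GRCm38 for 2.4%, so coordinates were taken from GENCODE M21 by identifier and never from the deposited table.

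Counts were tested as deposited in edgeR 4.0.16 under R 4.3.3, with filterByExpr, TMM scaling (factors 0.969 to 1.024), robust quasi-likelihood fits with group as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. FPKM values served only for the gene lengths. The biological coefficient of variation was 22.3%. Pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom 11.2 to 56.5), so no library was a copy of another. Simulated counts for the 13263 tested genes, with the real means, dispersions and library sizes and 200 genes changed in each of 5 runs, gave 62.4% of genes called at an absolute log2 fold change of 1 and 91.2% at 2, with 4.2% of calls false. The simulation draws genes independently and has no library that stands apart.

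The 38 gene lists (1042 members) were written before the data were examined. Of the members, 679 fell on a named row. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, against all named genes, and lists with under 5 tested members were left out. Benjamini-Hochberg adjustment ran over the 34 lists tested. In the same simulations, with no list shifted, camera called 0 of 170. Simulated genes were independent, so this cannot vouch for calls on lists whose members correlate. In the real data the estimated correlation within the lists called ran from 0.50 (endothelial) to 0.95 (skeletal muscle). A score of a list is the mean over members of log2 CPM centred per gene.

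The rule for named genes was set before the data were examined: up to 12 genes per direction past the threshold with no overlap between groups, a mean of at least 2 CPM in the higher group and an established symbol, filled to 5 by the smallest unadjusted p if fewer pass. Up to 4 members of a described list with the smallest p, and 7 fixed genes, were added. Of these 7, Mki67 was tested and Gpbar1 fell under the count filter, while Nfe2l2, Cd8a, S100a8, Adgre1 and Epcam were not assigned to a single row and are not analysed here. Cpa3, Siglecf, Cxcl9, Fasn, Acaca, Lpl, Ckm, Myh1, Tnni2, Prg2, Mylpf, Tgfbr1, Plin4, Cidec and the genes of the lists written afterwards are named besides this rule, after their values were seen, because a count or range pointed to them.

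Alternatives set beforehand were DESeq2 1.42.0, limma-voom with sample quality weights, other scalings and filters, the replicate number as a block, other thresholds, other list tests and leaving out each library. An alternative for a table without counts was not needed. Figures were drawn with matplotlib 3.10.9.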

Results

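The series compared tumours of mice given oleanolic acid, a plant triterpenoid, with tumours of mice given the drug solvent. Tumours were grown from 4T1 cells, a mouse mammary carcinoma line, placed under the skin of the flank of female BALB/c mice. Bulk RNA sequencing of tumour tissue gave 3 libraries of the oleanolic acid group (OA, 40 mg/kg by gavage; replicates 1, 6 and 7) and 3 of the solvent group (CK; replicates 1, 2 and 6). The protocol also describes a tamoxifen group and an uninjected group, which are not analysed here. Total gene counts per library lay between 14273215 and 17066402, and the 10 most abundant genes took between 5.11% and 5.95% of them. No label states that the 3 libraries of a group came from separate mice, so p-values measure the spread between these samples, part of which may be technical. After a filter on low counts 13263 genes were tested, and 9803 of them could be named from the deposited table. Values below are CPM, counts scaled to library size, as mean ± SD of 3 libraries, and log2 fold changes are OA against CK with their standard error.

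The first question was which genes differed between tumours of treated and solvent-treated mice. Genes at low and at high levels stood apart between the groups. Cma1, a mast cell chymase, was measured at 8.81 ± 0.321 CPM in OA and 2.27 ± 0.483 CPM in CK tumours (log2 fold change 1.95 ± 0.25). Wif1, a secreted Wnt inhibitor, stood at 2.33 ± 0.178 against 0.258 ± 0.0631 CPM (3.14 ± 0.41), and Wfdc18, a secreted protein of the mammary gland, at 2.64 ± 0.451 against 0.109 ± 0.097 CPM (4.52 ± 0.68). In the other direction, Thbs1, which encodes the matrix protein thrombospondin, was measured at 476 ± 84.2 CPM in OA and 945 ± 80.7 CPM in CK tumours (-0.99 ± 0.15). Abcc3, an export pump for organic anions and bile salts, stood at 70.7 ± 2.53 against 121 ± 11.7 CPM (-0.77 ± 0.10).

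None of these genes passed edgeR on the 6 libraries. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 genes had an adjusted p under 0.05, the lowest adjusted p was 0.112, and 1361 genes had an unadjusted p under 0.05 (700 higher and 661 lower in OA). DESeq2 called 240 genes and limma-voom with sample quality weights called 54 higher and 61 lower, giving CK replicate 6 a weight of 0.26 against 0.85 to 1.74 for the other libraries. The library of CK replicate 6 decided the edgeR count: without it 167 genes passed, 74 higher and 93 lower in OA. Without CK replicate 2 the count was 1, and without any other library 0. In 17.1% of the tested genes the 3 values of one group all lay above those of the other, against 10% by chance.

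As no gene passed, the 5 named genes per direction with the smallest p and no overlap between groups were taken, and none of the 10 passed edgeR with all 6 libraries. DESeq2 called all 10, and edgeR without CK replicate 6 called all but Atp6v1b1. Besides those above, Eml5, a microtubule-associated protein, stood at 42.2 ± 2.79 CPM in OA and 24.4 ± 0.747 CPM in CK tumours (log2 fold change 0.79 ± 0.11). Atp6v1b1, a proton pump subunit, stood at 2.22 ± 0.957 against 0.176 ± 0.0938 CPM (3.62 ± 0.61). Rapgef5, a guanine nucleotide exchange factor for Rap proteins, was measured at 9.41 ± 1.18 against 20.8 ± 0.238 CPM (-1.14 ± 0.15), and Pde4d, a cyclic AMP phosphodiesterase, at 18.9 ± 1.3 against 31.8 ± 1.71 CPM (-0.75 ± 0.12). Myog, the muscle transcription factor myogenin, had 2 reads over the OA and 108 reads over the CK libraries. That is a CK to OA ratio of 53.5 with a 95% interval of 14.5 to 447 (exact binomial, counting error only). Adjusted p-values of the 10 genes by edgeR ran from 0.112 to 0.226.

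**Figure D1:**
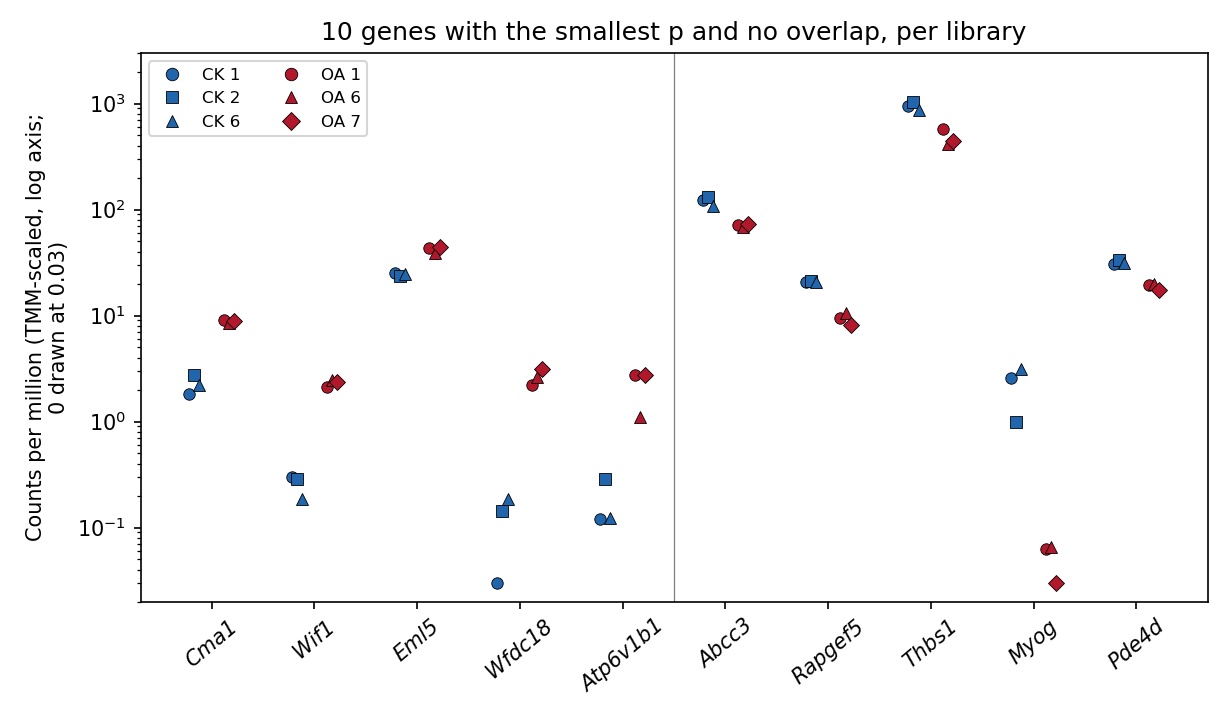
CPM on a log axis of the 10 genes, 1 point per library (blue CK, red OA, shapes give the replicate number), with the 5 genes higher in OA left of the line and the 5 lower genes right of it. In each gene all 3 libraries of one group lie above those of the other, as with Thbs1, whose groups average 476 and 945 CPM.

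On the GRCm38 assembly, in the GENCODE M21 annotation, all 10 are protein-coding genes. Cma1 (ENSMUSG00000022225) lies on chromosome 14 from 55941451 to 55944675, Wif1 (ENSMUSG00000020218) on chromosome 10 from 121033960 to 121100650, and Eml5 (ENSMUSG00000051166) on chromosome 12 from 98786805 to 98901484. Wfdc18 (ENSMUSG00000000983) lies on chromosome 11 from 83709015 to 83711348 and Atp6v1b1 (ENSMUSG00000006269) on chromosome 6 from 83742990 to 83758855. Abcc3 (ENSMUSG00000020865) lies on chromosome 11 from 94343295 to 94392997, Rapgef5 (ENSMUSG00000041992) on chromosome 12 from 117516479 to 117759737, and Thbs1 (ENSMUSG00000040152) on chromosome 2 from 118111876 to 118127133. Myog (ENSMUSG00000026459) lies on chromosome 1 from 134289989 to 134292548 and Pde4d (ENSMUSG00000021699) on chromosome 13 from 108449948 to 109953461.

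The second question was whether groups of genes moved together. Of 38 lists fixed beforehand, 34 had enough named members and 6 passed camera at an adjusted p under 0.05: skeletal muscle and endothelial genes fell in OA tumours, and cell cycle, cholesterol and fatty acid synthesis and antigen presentation genes rose, as did the list of mast cell and eosinophil genes in its mast cell members. At least as many lists passed in 8 of the 10 splits of the 6 libraries, the real one included, so the number of lists does not set treatment apart. With an estimated correlation in place of the preset one none of the 6 calls held (adjusted p = 0.956 with an estimated correlation, for each), and fry, which tests a list without reference to other genes, called 0 lists in 1 direction. Its mixed version, not among the planned tests, was under 0.05 for 6 lists: mast cell and eosinophil (adjusted p = 0.0107), interleukins (0.0107), angiogenesis (0.0107), oxidative phosphorylation (0.0107), nerve (0.0141) and TNF and TGF-beta ligands (0.0476). In edgeR with all 6 libraries no member of any list passed over all genes tested. Of the 6 lists that passed camera, DESeq2 called the members Cma1, Tpsab1, Fcer1a, Ube2c and H2-Q7 higher and Siglecf, Prg2, Cdh5, Cldn5, Mylpf, Myl1 and Mb lower in OA, and limma-voom called Cma1, Ube2c and H2-Q7 higher and Mb lower.

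Skeletal muscle genes showed the largest shift. The median log2 fold change of 14 measured members was -5.45 (camera adjusted p = 9.17e-07), all 14 had a negative value, and 9 fell when adjusted over the list alone. Acta1, skeletal muscle actin, was measured at 1.71 ± 1.26 CPM in OA and 273 ± 434 CPM in CK tumours. Myoglobin (Mb) stood at 0.453 ± 0.327 against 6.06 ± 4.57 CPM, the fast myosin light chain Myl1 at 0.473 ± 0.15 against 28.5 ± 43.0 CPM and the sarcomere protein Tcap at 0.0856 ± 0.0742 against 18.5 ± 29.8 CPM. The list's score per library, its members' mean log2 CPM centred per gene, was 4.85 in CK replicate 6, 0.50 in CK replicate 1 and -0.34 in CK replicate 2, and lay between -2.35 and -1.31 in the OA libraries. Without CK replicate 6 the median was -2.09 and the call held.

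Mast cell and eosinophil genes moved apart within their list. The median of 11 members was 1.35 (camera adjusted p = 2.0e-05). Adjusted over the list alone 5 members rose and 1 fell. The 5 were the mast cell genes Cma1, Fcer1a, Mrgprb1, Tpsab1 and Cpa3. Tpsab1, a mast cell tryptase, was measured at 34.6 ± 6.27 CPM in OA and 11.5 ± 7.04 CPM in CK tumours, the IgE receptor subunit Fcer1a at 1.72 ± 0.32 against 0.258 ± 0.0677 CPM, and the mast cell receptor Mrgprb1 at 2.32 ± 0.688 against 0.629 ± 0.232 CPM. The 1 that fell was Siglecf, a surface protein of eosinophils, at 0.235 ± 0.127 against 2.61 ± 3.09 CPM, with 6.18 CPM in CK replicate 6 and 0.787 and 0.854 CPM in CK replicates 1 and 2. Chymases and tryptases belong to families of close copies, so their counts are uncertain where reads fit several members.

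Endothelial genes fell by a median of 0.58 on the log2 scale over 14 members (camera adjusted p = 0.00025), with 12 of 14 negative and 0 past the threshold when adjusted over the list alone. The tight junction gene Cldn5 stood at 4.01 ± 1.66 CPM in OA and 10.3 ± 3.66 CPM in CK tumours, and Cdh5, the endothelial cadherin, at 32.9 ± 12.5 against 60.8 ± 5.03 CPM. Vwf, the von Willebrand factor, was measured at 6.5 ± 2.6 against 12.6 ± 4.37 CPM, and the guidance receptor Robo4 at 7.61 ± 1.97 against 11.8 ± 2.38 CPM. The median was -0.32 without OA replicate 7 and -0.82 without OA replicate 1. The endothelial scores of the groups overlapped, with 0.10 in OA replicate 1 and 0.08 in CK replicate 1.

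Cell cycle genes rose by a median of 0.40 over 21 members, all of them positive (camera adjusted p = 9.17e-07), of which 1 rose when adjusted over the list alone. That member was Ube2c, a subunit of the mitotic ubiquitin machinery, at 89.6 ± 13.6 CPM in OA and 51.8 ± 8.18 CPM in CK tumours. Cdc20 stood at 104 ± 25.4 against 71.4 ± 15.4 CPM, Cdk1 at 114 ± 13.3 against 89.8 ± 15 CPM and Cenpf at 194 ± 27.8 against 135 ± 37.7 CPM. The proliferation marker Mki67 stood at 393 ± 79.3 against 339 ± 103 CPM (0.21 ± 0.24, edgeR adjusted p = 0.793). The list median was 0.25 without CK replicate 2 or without OA replicate 6, and 0.58 without CK replicate 6. Cell cycle scores overlapped between groups: CK replicates 1, 2 and 6 had -0.10, -0.59 and 0.04, and OA replicates 1, 6 and 7 had 0.09, 0.50 and 0.04.

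Cholesterol and fatty acid synthesis genes rose by a median of 0.59 over 19 members, 17 of them positive (camera adjusted p = 3.46e-06), with 0 past the threshold when adjusted over the list alone. Hmgcs1, an early enzyme of the mevalonate pathway, stood at 102 ± 26.8 CPM in OA and 64.7 ± 17.6 CPM in CK tumours, and Mvk, mevalonate kinase, at 20.8 ± 4.85 against 13.8 ± 0.719 CPM. Dhcr7 was measured at 40.7 ± 0.153 against 32.5 ± 3.91 CPM and Fdps at 5.24 ± 2.73 against 2.46 ± 0.496 CPM. The 2 members with a negative value were the fatty acid enzymes Fasn and Acaca. The median was 0.33 without OA replicate 6, 0.39 without CK replicate 2 and 0.77 without CK replicate 6. The score was highest in OA replicate 6, at 0.72, and lowest in CK replicate 2, at -0.62. OA replicates 1 and 7, at 0.03 and 0.06, lay below CK replicate 6, at 0.09. OA replicate 6 also had the highest score of the skin list (1.11) and of the 4T1 and mammary epithelial list (0.81).

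Antigen presentation genes rose by a median of 0.25 over 8 members, all positive (camera adjusted p = 0.00293), and 3 rose when adjusted over the list alone. These were the non-classical MHC class I gene H2-Q7 (71.6 ± 7.27 CPM in OA and 41.3 ± 6.15 CPM in CK tumours) and the immunoproteasome subunits Psmb8 (72.9 ± 0.429 against 57.6 ± 5.34 CPM) and Psmb9 (200 ± 18.9 against 142 ± 26.9 CPM). The peptide transporter subunit Tap2 stood at 90.1 ± 3.95 against 69 ± 13.9 CPM. Without CK replicate 2 the median was 0.16 and the call was lost (camera adjusted p = 0.0661), and without CK replicate 6 the median was 0.51. With the replicate number as a block the call was lost as well (median 0.19, camera adjusted p = 0.094). H2-Q7 has near-identical neighbours, and its count is uncertain for that reason.

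**Figure D2:**
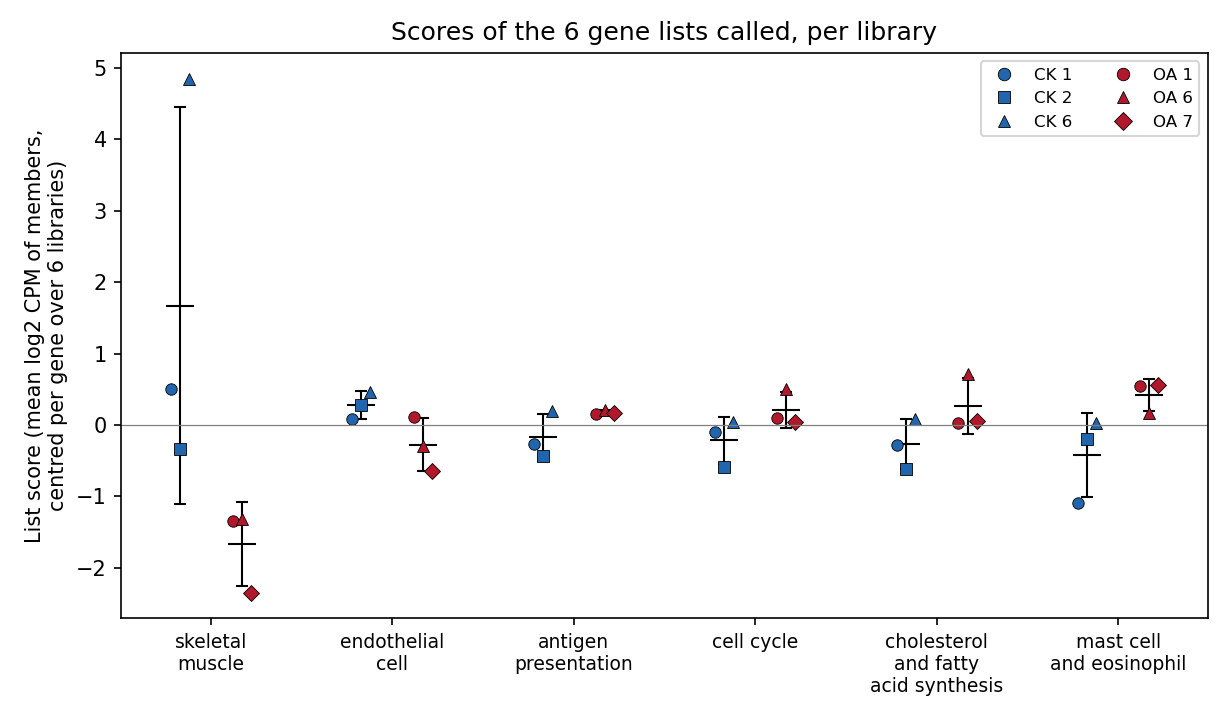
Scores of the 6 lists that passed camera (mean log2 CPM of a list's members, centred per gene over the 6 libraries), 1 point per library, with horizontal bars at group means and error bars of 1 SD. CK replicate 6 stands apart in the muscle list at 4.85, while groups overlap in the endothelial, antigen presentation, cell cycle and cholesterol lists.

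The cytokine and cytokine receptor genes named in the study's title were examined as 5 lists. These were chosen by the study on these samples and are not independent evidence of a direction. None passed camera with all 6 libraries and group as the only term, though the interleukin list did with the replicate number as a block. The median log2 fold change was -0.05 for 18 chemokine ligands (adjusted p = 0.906), 0.16 for 19 interleukins, interferons and colony-stimulating factors (adjusted p = 0.207), 0.03 for 16 TNF and TGF-beta family ligands (adjusted p = 0.906), -0.13 for 12 chemokine receptors (adjusted p = 0.906) and 0.09 for 57 cytokine receptors (adjusted p = 0.408). Over the fits leaving out 1 library the median ran from -0.50 to 0.44 for chemokine receptors and from -0.04 to 0.33 for the interleukin list. Adjusted over the list alone, 1 member passed in all 5 lists together, the TGF-beta family ligand Gdf11, at 18.5 ± 1.93 CPM in OA and 11.3 ± 1.38 CPM in CK tumours.

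Single cytokine genes with unadjusted p under 0.05 lay on both sides, more of them higher in OA. The interleukin list had 5 higher and 0 lower, and the cytokine receptors 5 higher and 1 lower. TNF and TGF-beta family ligands had 2 and 2, chemokine receptors 1 and 1, and chemokine ligands 0 and 1. Not all of the higher ones are named here. Il10, an anti-inflammatory cytokine, stood at 14.2 ± 5.89 CPM in OA and 3.31 ± 2.52 CPM in CK tumours, and Il7, a lymphocyte growth factor, at 16.4 ± 1.42 against 9.47 ± 2.14 CPM. Il34 was measured at 17.7 ± 2.81 against 12.9 ± 1.21 CPM and Il19 at 0.821 ± 0.102 against 0.366 ± 0.103 CPM. The death ligand Tnfsf10 stood at 85.7 ± 10.2 against 43.5 ± 19.5 CPM. Among receptors, the prolactin receptor Prlr was measured at 8.71 ± 3.85 against 0.535 ± 0.824 CPM, Il1rl1, the receptor of interleukin 33, at 15.1 ± 1.95 against 7.07 ± 3.59 CPM, Il17rc at 42 ± 6.32 against 28.7 ± 4.32 CPM and Il17rb at 2.3 ± 0.896 against 0.662 ± 0.391 CPM. Ccr10 stood at 1.27 ± 0.171 against 0.347 ± 0.199 CPM. The TGF-beta receptor Tgfbr1 was lower, at 189 ± 10.3 against 246 ± 39.7 CPM. Also lower in OA were Cx3cr1, the fractalkine receptor (22.1 ± 7.46 against 54.2 ± 23.9 CPM), the eosinophil attractant Ccl24 (11.9 ± 1.09 against 21.9 ± 8.24 CPM), Bmp2 (4.29 ± 1.71 against 9.96 ± 3.22 CPM) and Bmp7 (27.5 ± 0.767 against 36.4 ± 6.9 CPM). Without CK replicate 6 the cytokine receptor list rose (camera adjusted p = 0.00157), and edgeR called 4 genes of these lists higher in OA: Cxcl9, Tnfsf10, Il1rl1 and Prlr. With all 6 libraries DESeq2 called Tnfsf10 and Gdf11 higher and Cx3cr1 lower. The limma-voom fit, which gave CK replicate 6 little weight, called Tnfsf10, Il1rl1 and Prlr higher. Prlr is also a member of a mammary gland list written afterwards and described below.

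**Figure D3:**
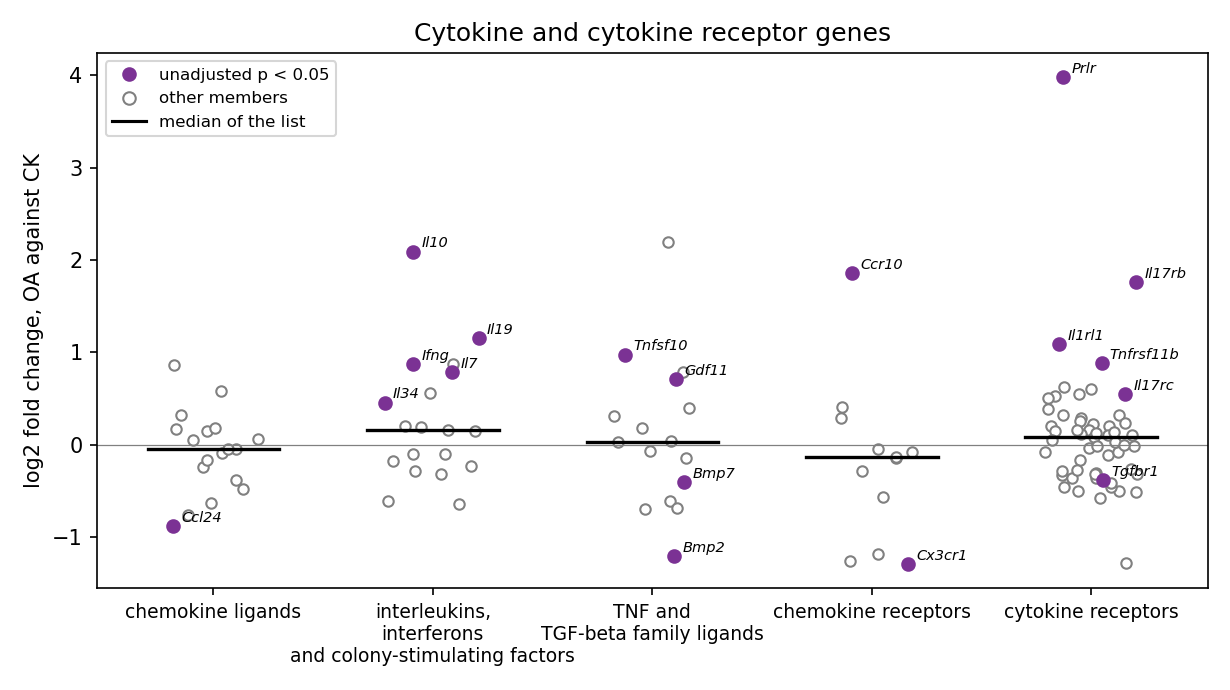
log2 fold change (OA against CK) of each named member of the 5 cytokine lists, with filled points for an unadjusted p under 0.05 and a bar at each list's median. The medians lie between -0.13 and 0.16.

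Besides the mast cell list, no lymphocyte or myeloid list passed with all 6 libraries under TMM scaling and group as the only term. Without CK replicate 6, dendritic cell genes (median 0.62, adjusted p = 0.000684) and cytotoxic and NK cell genes (0.68, adjusted p = 0.00157) rose, and neutrophil genes fell (-0.64, adjusted p = 0.0115). Cytotoxic and NK cell genes came closest, with a median of 0.21 over 14 members (camera adjusted p = 0.0522) and of -0.02 without OA replicate 1, where the NK cell receptor Ncr1 stood at 1.69 ± 0.446 CPM in OA and 0.572 ± 0.203 CPM in CK tumours and Ifng at 1.68 ± 0.357 against 0.913 ± 0.123 CPM. T cell genes had a median of -0.04 and a mean of -0.02 over 17 members while camera's direction was up (adjusted p = 0.759). Neutrophil genes had a median of -0.48 over 14 members (adjusted p = 0.207) and of -0.26 without CK replicate 2. Of these, Retnlg stood at 2.32 ± 0.823 against 10.9 ± 7.24 CPM and Lcn2 at 79.5 ± 31.4 against 220 ± 130 CPM, and 1 member, Retnlg, fell when adjusted over the list alone. Macrophage and monocyte genes had a median of -0.24 over 13 members (adjusted p = 0.207), with Gpnmb at 8.84 ± 1.19 against 15.7 ± 6.09 CPM. Their median was -0.48 without CK replicate 1 and 0.04 without CK replicate 6. Dendritic cell genes had a median of 0.01 and a mean of -0.08 over 13 members (adjusted p = 0.574). The 4 named B and plasma cell genes, with a median of -1.44, were too few to test. Without CK replicates 1 or 2 in turn, 8 members could be tested and fell (medians -2.50 and -2.48, adjusted p = 0.0273 and 0.0458). Without OA replicates 1, 6 or 7 they were testable and did not pass (adjusted p = 0.227, 0.526 and 0.153). Among them Jchain stood at 11.1 ± 6.42 against 36.1 ± 58.7 CPM, with 104 CPM in CK replicate 6 and 1.88 and 2.63 CPM in CK replicates 1 and 2.

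Lists of other tissues, apart from skeletal muscle and endothelial genes, also did not pass with all 6 libraries. Adipocyte genes had a median of -1.24 over 13 members (adjusted p = 0.848), with scores of 2.42 in CK replicate 6 and -1.29 and -1.50 in CK replicates 1 and 2. Without CK replicate 6 that median was 1.21 and the list rose (adjusted p = 0.000521), as did T cell genes (median 0.80, adjusted p = 0.0016) and fibroblast genes (median 1.20, adjusted p = 5.81e-05). With all libraries, fibroblast and pericyte genes had a median of 0.22 over 13 members (adjusted p = 0.207), with Pdgfra at 119 ± 11.5 CPM in OA and 84.3 ± 12.3 CPM in CK tumours. Medians were 0.21 for 10 epithelial genes of 4T1 and mammary cells (adjusted p = 0.846), -0.20 for 8 peripheral nerve genes (adjusted p = 0.574) and -0.85 for 5 red blood cell genes (adjusted p = 0.24). Adjusted over the list alone 1 epithelial gene rose, the basal keratin Krt5 (12.6 ± 14.3 against 0.177 ± 0.155 CPM), and 2 nerve genes fell, Mbp (39.8 ± 0.791 against 52.9 ± 1.87 CPM) and Ncmap (6.78 ± 1.93 against 12.9 ± 1.23 CPM). The 4 named skin genes, with a median of 0.15, were not tested, and the epidermal keratin Krt10 among them was at 47.5 CPM in OA replicate 6 and at most 2.54 CPM elsewhere.

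Signalling and stress lists gave the following medians. Angiogenesis factors had -0.30 over 24 members (adjusted p = 0.0728), with 1 rising and 2 falling when adjusted over the list alone: Vegfc, a lymphatic growth factor, stood at 15.5 ± 3.58 CPM in OA and 7.11 ± 1.03 CPM in CK tumours, and Pdgfb fell with Thbs1, at 36 ± 3.28 against 53.8 ± 5.42 CPM. Thbs1 encodes an inhibitor of angiogenesis, and the list as written shares Flt1, Kdr and Tek with the endothelial list. The median of this list therefore gives no direction of angiogenesis. Targets of NRF2, a stress factor that oleanane triterpenoids are known to engage, had a median of 0.01 and a mean of -0.03 over 15 members (adjusted p = 0.906). Among them Osgin1 stood at 16.6 ± 0.732 against 24.2 ± 2.52 CPM and Nqo1 at 4.56 ± 1.77 against 2.85 ± 0.565 CPM. Of the bile acid receptors and targets 4 named genes were measured, with a median of -0.28 and too few to test, and Gpbar1, a bile acid receptor that oleanolic acid activates, had 0 reads in the 3 OA libraries and at most 2 in a CK library. The median was -0.01 for 17 apoptosis and p53 genes (adjusted p = 0.864), 0.12 for 15 interferon response genes (adjusted p = 0.42), -0.15 for 13 immune checkpoint genes (adjusted p = 0.602) and 0.02 with a mean of -0.06 for 17 NF-kB and inflammation genes (adjusted p = 0.864).

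Apart from cholesterol and fatty acid synthesis, metabolic and structural lists likewise did not pass with all 6 libraries and group as the only term. Hypoxia and glycolysis genes had a median of -0.10 over 14 members (adjusted p = 0.338), with hexokinase Hk2 at 144 ± 9.65 CPM in OA and 195 ± 23.6 CPM in CK tumours. Extracellular matrix and protease genes had a median of -0.08 over 19 members (adjusted p = 0.309), with the basement membrane collagens Col4a1 at 593 ± 63.2 against 826 ± 86.5 CPM and Col4a2 at 314 ± 39 against 453 ± 45.9 CPM. Epithelial-mesenchymal transition genes had -0.16 over 12 members (adjusted p = 0.725) and unfolded protein response genes 0.01 over 13 members (adjusted p = 0.906). The transition list was written with both epithelial genes, such as Cdh1, and mesenchymal genes, such as Vim. A transition would move these in opposite directions, so neither the list's median nor camera can decide whether one took place. Heat shock and immediate early genes had -0.23 over 14 members (adjusted p = 0.26), nuclear oxidative phosphorylation genes 0.07 over 19 members (adjusted p = 0.348) and cytosolic ribosomal proteins -0.06 over 14 members (adjusted p = 0.795). The 3 named mitochondrially encoded genes, with a median of 0.30, were not tested. The mitochondrial gene mt-Cytb stood at 3726 ± 367 against 3028 ± 367 CPM.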

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

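The edgeR counts of genes stayed at 0 in both directions with relative log expression or upper-quartile scaling, with no count filter and with a mean count of at least 50. A minimum log2 fold change of 1, set on top of the main fit, could only leave the counts at 0 and checks nothing. Leaving out 1 library gave 0 to 74 genes higher and 0 to 93 lower in OA, where all but 1 of the calls came without CK replicate 6. DESeq2 called 95 higher and 145 lower, limma-voom 54 and 61, and an unadjusted p under 0.05 with an absolute log2 fold change of at least 1 gave 110 and 127. In alternatives chosen after seeing the data, DESeq2 without CK replicate 6 called 509 higher and 424 lower, and edgeR with the adipocyte score as a covariate called 46 and 75. The cause of the gap between tools was not tested. Of the genes DESeq2 called, 77 were also called by edgeR without CK replicate 6.

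Lists passing camera numbered 6 to 17 when 1 library was left out, with 17 without CK replicate 6, against 6 with all. The number was 7 with relative log expression scaling, which added cytotoxic and NK cell genes (camera adjusted p = 0.0452), and 6 with a mean count of at least 50. It was 0 with an estimated correlation and 0 with fry. With only rows named by length alone, chosen after seeing the data, 11 lists could be tested and 3 passed: skeletal muscle, cell cycle, and cholesterol and fatty acid synthesis. Endothelial genes, with 7 members, lost their call (median -0.69, adjusted p = 0.0661), and mast cell and antigen presentation lists had too few members. T cell genes ranged from a median of -0.36 to 0.80 and adipocyte genes from -1.83 to 1.21 over the fits leaving out 1 library. Both passed as higher without CK replicate 6. The T cell median, for which camera gave the direction as higher with all libraries, was also positive without OA replicate 6 (0.20) and without OA replicate 7 (0.03), where the list did not pass. Among named genes, 2 turned direction with a call in DESeq2 without CK replicate 6: Jchain at 2.30 and Thrsp at 5.73, the latter a fitted value against libraries at 0 and no bound. Signs changed without a call in 43 of 2343 values of named genes and 49 of 384 values of lists, such as Fabp4 (-0.98, and 0.45 without CK replicate 6). The 384 include the tests with an estimated correlation and with fry, which reuse the main medians and so could not change sign. Outside the named genes, edgeR without CK replicate 6 called Plin4 at 3.40 and Cidec at 3.88, against -1.24 and -1.43 with all libraries.

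Other lists that did not pass in the planned camera test of all libraries passed with 1 left out. Without CK replicate 6 these were interferon response (adjusted p = 0.0458) and NF-kB genes (0.0117) as higher and hypoxia (0.00478) and ribosomal genes (0.000291) as lower. Angiogenesis factors were lower without OA replicate 1 (0.00835) or CK replicate 1 (0.0287), macrophage genes without OA replicate 1 (0.0126) and heat shock genes without CK replicate 1 (0.0287). Cytotoxic genes were higher without OA replicate 6 (0.00812) or 7 (0.0142), but had a median of -0.02 without OA replicate 1 (0.385) and of 0.11 with a mean count of at least 50 (0.42). They also passed with relative log expression scaling and with the replicate block, as did heat shock genes with the block. Higher as well were fibroblast genes without OA replicate 7 (0.0292).

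The replicate block rests on numbers 1 and 6 alone, which occur in both groups. Deviations of same-numbered libraries correlated at -0.27 and -0.05, which gives no sign of pairing. With 2 shared numbers, and CK replicate 6 standing apart within its group, these values cannot exclude it. With the replicate block edgeR called 2 genes higher and 0 lower, and 8 lists passed: antigen presentation did not, while interleukins (camera adjusted p = 0.0201), cytotoxic and NK cell genes (adjusted p = 0.0437) and heat shock genes (adjusted p = 0.0201) did.

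No named gene changed sign under another scaling or filter. Medians of the dendritic cell and unfolded protein response lists, both near 0, did. The alternative planned for a table with FPKM values only was not run, as the table holds counts.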

Other observations

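All tests of explanations below, with the values they had to meet, were chosen after the results they bear on had been seen. The fit without CK replicate 6 that some of them use was planned beforehand.

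Mammary gland genes differed between groups in a list written after many of their values had been seen, so the following are values and not a test. Of 23 named members 22 were higher in OA, and in 13 all OA libraries lay above all CK libraries. The score was 0.90, 0.89 and 0.96 in OA replicates 1, 6 and 7, and -1.12, -1.24 and -0.38 in CK replicates 1, 2 and 6. The progesterone receptor Pgr was measured at 0.944, 1.18 and 1.52 CPM in the OA libraries and at 0 to 0.062 CPM in the CK libraries, and Ptn, a heparin-binding growth factor, at 8.19 to 13.2 CPM in OA and 0.142 to 2.78 CPM in CK tumours. Targets of the transcriptional regulator YAP, also listed after the fact, had a median log2 fold change of -0.22 over 18 members, with 3 positive and 6 in which all OA libraries lay below all CK libraries. Of these members Thbs1, Amotl1, Amotl2 and Nuak2 were called lower in OA by DESeq2, by limma-voom and by edgeR without CK replicate 6. Amotl2 had 49.2 to 57.9 CPM in OA and 73.0 to 100 CPM in CK libraries, while Axl, another target, had a log2 fold change of 0.01.

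Several rows with a small p stayed open between a few genes. A row that belongs to Ccn2 or P4hb stood at 71.7 ± 14.5 CPM in OA and 174.5 ± 11.5 CPM in CK tumours (edgeR adjusted p = 0.112). A row of Mcpt4 or Magea1 stood at 12.4 ± 2.51 against 2.15 ± 0.702 CPM, and a row of Ino80b or Tpsb2 at 22.7 ± 2.99 against 6.57 ± 2.61 CPM. Mcpt4 and Tpsb2 encode mast cell proteases.

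With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes, as did each of the others, so that 10 of 10 gave as many. No split can give fewer than 0, so this count decides nothing. At an unadjusted p under 0.05 it gave 1361 genes and the highest other split 1206, so that 1 of 10, the real one, gave as many. It gave 6 lists by camera and the highest other split 17, and 8 of 10 splits gave as many. Splits with 17 and 14 lists point to structure among the libraries other than treatment.

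Skeletal muscle genes were lower in OA tumours, and muscle in CK replicate 6 alone is argued against as the whole cause, since without that library the list's median was -2.09 and the list still passed. Whether CK replicates 1 and 6 held muscle of 1 makeup stays open: the ratio of their excess over OA spanned 20.3 times over members at 50 CPM or more in CK replicate 6 and above OA in both, but 3.21 times once Ckm, at 1.15 CPM in CK replicate 1, was left out. With Mb, at 11.3 CPM in CK replicate 6 and a ratio of 3.17, these spans were 102 and 16.2 times, so the answer hangs on single members. Myh1 and Tnni2, at 185 and 100 CPM in CK replicate 6, had no such ratio, as they were not above the OA mean in CK replicate 1, against what 1 makeup would give. Different amounts of muscle taken with the tumours, or an effect of treatment on muscle near the tumour, could both give such values and were not tested.

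Mast cell genes were higher in OA tumours. A lower share of tumour cells would raise mast cell and endothelial genes together. The score of the mast cell and eosinophil list minus the endothelial score was 0.699 ± 0.434 in OA and -0.699 ± 0.416 in CK libraries (SD, n = 3), a change of 1.40. Both lists were picked after camera had called them in opposite directions, so this gap cannot decide. Without CK replicate 6, fibroblast (median 1.20), adipocyte (1.21), T cell (0.80), cytotoxic (0.68) and dendritic cell genes (0.62) rose. Endothelial (-0.44), neutrophil (-0.64) and skeletal muscle genes (-2.09) fell there. A lower share of tumour cells stays open. Normal mammary gland in the OA pieces may have brought mast cells with it. The mammary gland score differed by 1.83, but that list was chosen from these values, so this source and treatment cannot be told apart. An effect of treatment on mast cells remains open and untested.

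CK replicate 6 decided how many genes edgeR called. Shallow sequencing is argued against by its total of 15.85 M counts, within the range of the other libraries. Fat and stroma in that piece could be another cause and stay open: of the 14 cell type lists other than the tumour cells' own, it had the highest score in 10, but not in cytotoxic and NK cell, neutrophil, mast cell and skin lists. The adipocyte lipase Lpl stood at 70.5 CPM there and at 4.54 and 5.05 CPM in CK replicates 1 and 2. Whether the piece or the mouse differed was not tested.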
